A study of Mus musculus with 29 samples.

How the data were processed

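Liver RNA of male C57BL/6N mice was measured on 29 Affymetrix arrays, 1 per mouse as the labels read. Livers were taken 1, 3, 7 or 21 days after ligation of the extrahepatic common bile duct or a sham operation. Groups come from the treatment and time labels. Titles carry different animal numbers, so p-values measure the spread between these animals. Replicate numbers are accession order and name an array only. This gave 7 groups.

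The deposited values are on a log2 scale. They were made with oligo 1.52.0 and RMA, per the submitters' processing notes. RMA subtracts background, brings all arrays to a shared distribution and summarises the probes of a row. Where high levels near the scanner's ceiling are compressed, as can be the case for Alb, differences come out smaller. Which arrays were normalized together is not given in the sources used here. The labels' protocols name the Mouse Genome 430 2.0 array, while the row identifiers match the platform annotation of another Affymetrix design, Mouse Gene 2.0 ST; gene names were taken from that annotation. Labelling with oligo dT primers is described per the labels' protocols.

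Of 41345 rows, 25335 were annotated, 23521 with 1 gene symbol and 1814 with several, and 16010 are unnamed here. Symbols were updated by gene ID through a RefSeq gene table of assembly GRCm38.p6, which held 23328 of the 1-symbol rows. The authors' genome build is not given in the sources used here, so no coordinates are printed. Rows with several symbols were not named. For a gene with several rows the row of highest mean was kept, which left 22180 genes, of which 14699 exceeded a log2 value of 5 in at least 3 arrays and were tested. Members of the Mup, Cyp2c, Cyp2d, Cyp3a, Cyp4a, Ces, Serpina, Ugt2b and Sult families share near-identical copies, so their values are uncertain. Slc51b, Spp1 and Saa1, which were to be reported always, were not analysed here, and a further item is not reported here.

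A linear model with 1 mean per group was fitted to all 29 arrays in limma 3.58.1 under R 4.3.3 (lmFit, eBayes), so all groups share an estimate of the spread. Two-sided adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. The comparisons were BDL against sham of the same day at days 1, 3 and 7, BDL at day 21 against sham at day 7, successive days of BDL, the earlier sham days against day 7, and the effect of BDL at day 7 minus that at day 1. Fold changes are differences of group means of log2 values, first-named group minus second. A group mean under the filter level of 5 was not told apart from background, as for 61 of 271 named calls. The size of such a change depends on the background and gives no rank. For some genes that lead a comparison the step between brighter mean and filter level is given as the least size.

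Before the data were examined, the comparisons, the test, the gene lists, the alternatives except those said to be added, and the rule for named genes were fixed. For each comparison of BDL with sham the rule takes the 10 largest rises and 10 largest falls past the threshold whose arrays do not overlap between the groups, and 5 each for the other comparisons. It adds up to 4 members per list with the largest change, and 24 genes of cholestasis, ducts, scar, inflammation, growth and zonation whatever their result. Predicted genes named Gm, Rik or LOC were passed over. Where the text names fewer list members, the ones with the largest changes not named already or those always reported were taken.

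The 32 gene lists held 578 genes, 487 of them measured. They cover bile acid synthesis, uptake, canalicular export and sinusoidal export, hepatocyte transcription factors, secreted plasma proteins, pericentral and periportal genes, cytochromes P450, male-biased and female-biased genes, fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, NRF2 targets, the unfolded protein response, the circadian clock, the cell cycle, acute phase and interferon responses and cytokines. Marker lists stand for cholangiocytes, stellate cells and matrix, Kupffer cells, monocyte-derived macrophages, neutrophils, lymphocytes, sinusoidal endothelium, exocrine pancreas, adipocytes, mesothelium and erythroid cells. Lists were tested with limma's camera at a preset correlation of 0.01 between genes and again with an estimated correlation. Where the p of a called list in camera stands alone, the list also passed with the latter. Of 144 called lists over all comparisons, 21 passed with the estimated correlation, and 109 with fry, which asks whether a list's genes move on balance one way.

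The procedure was tested on simulated data with 200 of 14699 genes changed. At a log2 change of 1, 97.0% were called for day 1, 89.6% for day 3, 98.5% for day 7, 91.0% for day 21 and 71.6% for the difference between days 7 and 1. The simulated genes were independent of each other, as real ones are not.

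Alternatives were no filter, a stricter filter, the mean of a gene's rows, quantile, cyclic loess or median scaling, a mean-variance trend with a robust prior, array weights, only the groups compared, other sham groups as control, and leaving out each array in turn. Terms for the array set, and fits without or within its arrays, were added after the data were seen. The set holds arrays whose SD of log2 values lies under 1.6. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.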

Results

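Gene expression was measured in whole livers of male C57BL/6N mice after ligation of the common bile duct, which stops bile flow into the gut, and after a sham operation without ligation. The labels give 29 Affymetrix arrays in 7 groups. There were 3 sham arrays at day 1, 2 at day 3 and 4 at day 7. Bile duct ligation (BDL) has 5 arrays at each of days 1, 3, 7 and 21. For day 21 no sham group was analysed here. Its BDL arrays were set against the sham arrays of day 7, and time after surgery and ligation cannot be separated in that comparison. Arrays have no sequencing depth, and their number limits the precision. The median SE of a log2 fold change was 0.151 at day 1, 0.173 at day 3 and 0.138 at day 7.

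The array medians lay between 4.90 and 5.13 on the log2 scale, and pairs of arrays correlated across genes at 0.889 to 0.990. Of the day 1 arrays, 4 stood apart from all others: sham day 1 replicates 1 and 3 and BDL day 1 replicates 2 and 3. The SD of their log2 values was 1.55 to 1.58, against 1.64 to 1.70 in the other arrays. Their mean over 76 genes of small nucleolar RNAs was 8.98 to 9.44, against 7.71 to 8.48. These 4 arrays are 2 of the 3 sham and 2 of the 5 BDL arrays of day 1, an unequal share. Counts of genes and list calls that use day 1 are therefore also given with this array set as a term of the model. That term passed for 3734 genes, 1075 higher and 2659 lower in the 4 arrays.

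**Figure D1:**
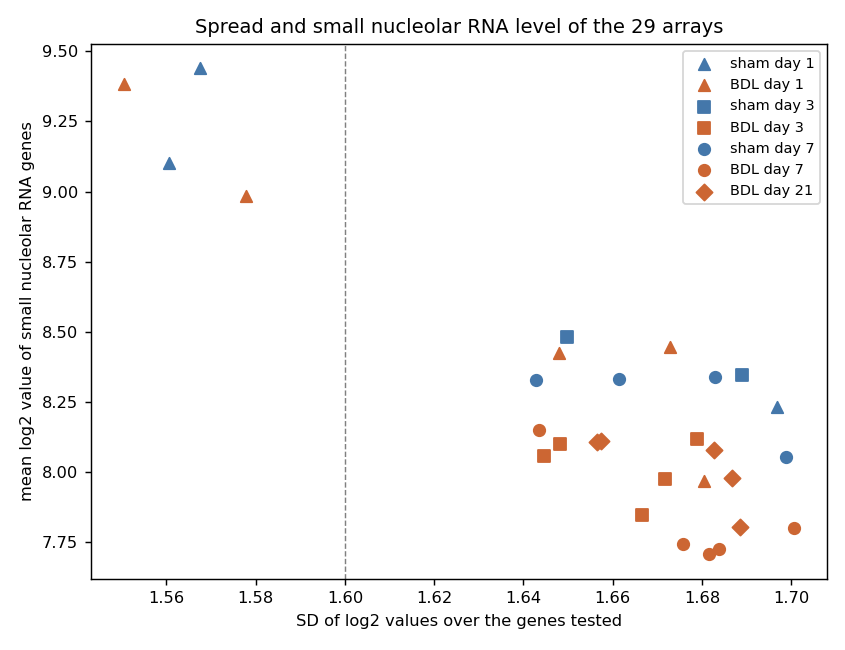
SD of the log2 values over the genes tested (x axis) against the mean log2 value of 76 small nucleolar RNA genes (y axis), 1 point per array, coloured by operation and shaped by day. The 4 day 1 arrays of low spread sit left of the dashed line at an SD of 1.6.

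At day 1, the first time point after the duct was blocked, enzymes of bile acid synthesis were among the largest falls. Here and for the later days, largest means by measured fold change among changed genes whose arrays did not overlap. Cyp7a1 (log2 fold change -5.65 ± 0.86 SE, as for the genes that follow), the rate-limiting enzyme of the classical pathway, stood at a log2 value of 4.29 ± 0.96 (SD, n = 5) in BDL and 9.94 ± 1.06 (SD, n = 3) in sham, a fall of at least 4.94 to the filter level of 5. Cyp8b1 (-5.07 ± 0.42), the hydroxylase needed for cholic acid, stood at a log2 value of 5.16 ± 0.36 (SD, n = 5) in BDL and 10.23 ± 0.30 (SD, n = 3) in sham. Both changes passed in limma, with adjusted p of 4.5e-05 and 3.42e-09. Other large falls were those of Car3 (-5.49 ± 0.71), a carbonic anhydrase, Hsd3b5 (-5.11 ± 0.44), a male-biased steroid dehydrogenase, and Serpina6 (-3.93 ± 0.60), which encodes corticosteroid-binding globulin. Inmt (-3.68 ± 0.57), the sulfotransferase Sult2a8 (-3.60 ± 0.27), Moxd1 (-3.36 ± 0.83), G6pc (-3.23 ± 0.64), the last enzyme of gluconeogenesis, and Cyp2c54 (-3.21 ± 0.42) fell too. The largest rises were those of Gstm3 (3.61 ± 0.50), a glutathione transferase, Cdkn1a (3.44 ± 0.32), an inhibitor of cyclin-dependent kinases, Chil3 (3.16 ± 0.42), a chitinase-like protein of macrophages, and Cd14 (3.14 ± 0.33), a co-receptor for lipopolysaccharide. Sprr1a (2.95 ± 0.45), the drug export pump Abcb1a (2.93 ± 0.25), Ccl2 (2.85 ± 0.29), a chemokine that attracts monocytes, Cib3 (2.85 ± 0.36), the basement membrane protein Nid1 (2.78 ± 0.22) and Sult1e1 (2.78 ± 0.49), the estrogen sulfotransferase, rose too. Among these 20 genes the highest adjusted p was 0.00629. A group mean under 5 was found for Cyp7a1, Hsd3b5, Chil3, Sprr1a and Sult1e1, and among list members for Slc22a30, S100a8 and Timp1, so their sizes have no rank.

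Bile acid synthesis genes fell in 8 of 16 and rose in 1 (9 and 1 adjusted over the list alone), Cyp7b1 (-2.33 ± 0.29) of the alternative pathway included. Camera placed bile acid synthesis down (adjusted p = 7.9e-07, adjusted p = 0.111 with an estimated correlation). Of 9 uptake transporters 6 fell and 1 rose (6 and 1 adjusted over the list alone), down in camera (adjusted p = 0.000698, adjusted p = 0.174 with an estimated correlation). Lower were Slc22a30 (-2.19 ± 0.44), Slc22a7 (-2.14 ± 0.31) and the organic anion carrier Slco1a1 (-2.14 ± 0.37), while Slc10a2 (1.36 ± 0.23), a bile acid carrier of cholangiocytes and the ileum, rose. The hepatocyte bile acid carrier Slc10a1 fell by 1.08 ± 0.24. Pericentral genes fell in 9 of 18 (12 adjusted over the list alone), with Cyp2c50 (-2.54 ± 0.33), Cyp2c37 (-2.04 ± 0.22) and Glul (-1.76 ± 0.31), the glutamine synthetase of the innermost pericentral cells. Camera placed pericentral genes down (adjusted p = 1.15e-09, adjusted p = 0.111 with an estimated correlation). Of 30 cytochromes P450 9 fell and 3 rose (14 and 5 adjusted over the list alone), down in camera (adjusted p = 2.99e-05, adjusted p = 0.195 with an estimated correlation). Cyp2e1 (-0.68 ± 0.12) fell and Cyp3a11 (0.94 ± 0.19) rose. Male-biased genes fell in 8 of 17 and rose in 1 (10 and 1 adjusted over the list alone), down in camera (adjusted p = 3.24e-07, adjusted p = 0.111 with an estimated correlation). Of 21 fatty acid oxidation genes 10 fell and 2 rose (14 and 2 adjusted over the list alone), Acaa1b (-1.34 ± 0.32) first. Camera placed the oxidation genes down (adjusted p = 3.82e-06, adjusted p = 0.173 with an estimated correlation). Secreted plasma proteins fell in 8 of 26 and rose in 1 (13 and 1 adjusted over the list alone), down in camera (adjusted p = 3.41e-05, adjusted p = 0.248 with an estimated correlation). Of 19 hepatocyte transcription factors 4 fell and 1 rose (5 and 2 adjusted over the list alone), with Cebpa (-1.17 ± 0.14), Ppara (-1.06 ± 0.16) and the bile acid receptor Nr1h4 (-1.0 ± 0.13) lower. Camera placed these factors down (adjusted p = 0.0171, adjusted p = 0.126 with an estimated correlation). Albumin was at 0.05 ± 0.07 (adjusted p = 0.746).

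Lists of cholesterol synthesis, stress and inflammation moved up. Cholesterol synthesis genes rose in 12 of 19 and fell in 1 (14 and 1 adjusted over the list alone), led by Lss (1.95 ± 0.33) and Sqle (1.67 ± 0.35), which together turn squalene into lanosterol. Camera placed cholesterol synthesis up (adjusted p = 3.22e-07, adjusted p = 0.238 with an estimated correlation). Of 15 NRF2 target and glutathione genes 9 rose (11 adjusted over the list alone), the heme oxygenase Hmox1 (1.77 ± 0.20) among them. Camera placed NRF2 targets up (adjusted p = 1.17e-08, adjusted p = 0.111 with an estimated correlation). Unfolded protein and stress response genes rose in 6 of 17 (10 adjusted over the list alone), led by Atf3 (1.37 ± 0.24). Camera placed the stress genes up (adjusted p = 3.05e-06, adjusted p = 0.111 with an estimated correlation). Of 25 acute phase genes 8 rose (10 adjusted over the list alone), with Steap4 (2.13 ± 0.21) and Saa3 (1.94 ± 0.41). Camera placed acute phase genes up (adjusted p = 6.23e-07, adjusted p = 0.195 with an estimated correlation). Cytokines and adhesion molecules rose in 9 of 23 (14 adjusted over the list alone), with Tnfaip3 (1.89 ± 0.17) and Cxcl1 (1.79 ± 0.36). Camera placed this group up (adjusted p = 9.36e-08, adjusted p = 0.111 with an estimated correlation). Of 13 neutrophil markers 8 rose (8 adjusted over the list alone), S100a8 (1.71 ± 0.37) among them. Camera placed the list up (adjusted p = 0.000746, adjusted p = 0.195 with an estimated correlation). Monocyte-derived macrophage markers rose in 6 of 15 (9 adjusted over the list alone), with Itgam (1.36 ± 0.24). Camera placed the macrophage markers up (adjusted p = 0.000250, adjusted p = 0.191 with an estimated correlation). Of 15 sinusoidal endothelial markers 7 fell (8 adjusted over the list alone), with Dnase1l3 (-1.46 ± 0.27) and Kdr (-1.31 ± 0.20), a receptor for vascular endothelial growth factor. Camera placed endothelial markers down (adjusted p = 2.51e-05, adjusted p = 0.195 with an estimated correlation).

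Most duct and scar genes were not past the threshold at day 1. Sox9 (1.46 ± 0.27), a transcription factor of the biliary lineage, and Timp1 (0.82 ± 0.27), an inhibitor of matrix proteases, rose. Krt19 and Krt7, keratins of bile ducts, were at 0.20 ± 0.14 and 0.12 ± 0.21. Col1a1 and Col1a2, the chains of type I collagen, were at 0.49 ± 0.55 and 0.32 ± 0.45, and Acta2 at 0.54 ± 0.30. Lcn2 was at 1.23 ± 0.43 and the proliferation marker Mki67 at -0.40 ± 0.25, and none of these 7 genes had an adjusted p under 0.0542. The bile salt export pump Abcb11 (0.57 ± 0.23), the export pump Abcc4 (0.16 ± 0.16) and the repressor Nr0b2 (1.0 ± 0.38) did not pass either. The camera test did not pass for cholangiocyte markers (median 0.17, adjusted p = 0.126), matrix genes (-0.04, 0.789), Kupffer cell markers (-0.37, 0.0865) or cell cycle genes (-0.14, 0.173). Nor did it for canalicular export (median 0.01, adjusted p = 0.544), sinusoidal export (0.19, 0.126), periportal genes (-0.27, 0.157), fatty acid synthesis (0.04, 0.876) or the circadian clock (-0.19, 0.237). The interferon list had a median of -0.09 and a mean of 0.08, of opposite sign (adjusted p = 0.795).

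Markers of tissue from outside the lobule did not pass as lists at day 1. They were those of exocrine pancreas (median 0.01, adjusted p = 0.918), mesothelium (-0.08, 0.612) and erythroid cells (0.25, 0.918). Adipocyte markers had a median of -0.04 and a mean of 0.24 (adjusted p = 0.898). Female-biased genes (median 0.08, adjusted p = 0.824) and lymphocyte markers (-0.16, 0.119) did not pass either.

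Across the genes tested, 1958 changed at day 1, 1252 higher and 706 lower in BDL, 199 and 142 of them by at least 2-fold. With cyclic loess scaling the split was 1106 higher and 1020 lower. With the array set as a term 2184 genes changed, 1207 higher and 977 lower, and 1762 genes were called both ways. Within the 4 arrays of low spread 1364 genes changed. Fold changes there correlated at 0.654 over all genes with those in the other day 1 arrays, which hold 1 sham array. All 16 lists called at day 1 were called in the same direction with the array set as a term, and no median moved by more than 0.136. The count was 1268 without sham day 1 replicate 1 and 1299 without replicate 3, 597 without the 4 arrays, 704 with only day 1 arrays in the fit and 3198 against all 9 sham arrays. Leaving out 1 array at a time ended the call of Moxd1 (without sham day 1 replicate 1, adjusted p up to 0.0526) and Timp1 (without BDL day 1 replicate 1, 3 or 5 or sham day 1 replicate 2 or 3, up to 0.174). Without the 4 arrays a lone sham array is left, assumed to vary like the other groups, and Cyp7a1 (-4.65), Moxd1 (-3.67), G6pc (-3.40), Cib3 (1.95), Sult1e1 (2.36), Slc10a1 (-1.18), Glul (-1.67), Cyp3a11 (0.47), Acaa1b (-1.27), Sqle (1.66), S100a8 (1.88) and Timp1 (1.20) did not pass there (adjusted p up to 0.424), while Saa3 was at 3.26. Within the 4 arrays Moxd1 (-3.05), Acaa1b (-1.32), Sqle (1.42), Saa3 (0.97), S100a8 (1.39), Sox9 (0.92) and Timp1 (0.58) did not pass (up to 0.383), nor did the transcription factor, neutrophil and endothelial lists (up to 0.141), and Sprr1a was at 1.63. Saa3 was at 3.71 against all 9 sham arrays. With only day 1 arrays the calls of Cxcl1 and Timp1 were lost (up to 0.0606). Calls were gained for Lcn2 (in 4 settings, adjusted p down to 5.48e-05), Abcb11 (in 3 settings, 1 of them without sham day 1 replicate 2, down to 0.00185) and Nr0b2 (in 4 settings, 1 of them without sham day 1 replicate 2, down to 0.000304). The transcription factor list did not pass without sham day 1 replicate 2 (adjusted p = 0.0876).

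At day 3, against the day's own sham group, Sult2a8 (log2 fold change -6.62 ± 0.31 SE, as for the genes that follow) fell from 11.16 ± 0.46 (SD, n = 2) to 4.53 ± 0.27 (SD, n = 5), a fall of at least 6.16 to the filter level. Car3 (-5.97 ± 0.82), Slco1a1 (-5.84 ± 0.42), Hsd3b5 (-5.58 ± 0.51), Cyp8b1 (-5.36 ± 0.48) and the fatty acid elongase Elovl3 (-4.62 ± 0.54) fell too. So did the major urinary protein genes Mup21 (-4.33 ± 0.41) and Mup-ps12 (-4.06 ± 0.57), the carboxylesterase Ces1f (-3.97 ± 0.78) and Cyp2c54 (-3.96 ± 0.48). Several of these belong to families of near-identical genes, so their values are uncertain. The largest rises were those of Sult1e1 (4.74 ± 0.56), Chil3 (4.25 ± 0.49), Sprr1a (4.08 ± 0.52), Obp2a (3.93 ± 0.96) and Gpnmb (3.79 ± 0.34), a glycoprotein of lipid-laden macrophages. Cxcl14 (3.24 ± 0.43), Cib3 (3.03 ± 0.41), Cdkn1a (2.90 ± 0.37), Marco (2.70 ± 0.34), a scavenger receptor of Kupffer cells, and the kinase Sik1 (2.68 ± 0.27) rose as well. No adjusted p of these 20 genes exceeded 0.00728 in limma, with 5 BDL and 2 sham arrays. Group means lay under 5 for Sult2a8, Slco1a1, Hsd3b5, Mup21, Mup-ps12, Sult1e1, Chil3, Sprr1a and Gpnmb, and in the lists for Timp1. Cyp7a1 fell by 3.43 ± 0.99 (adjusted p = 0.0230), BDL replicates 1 and 2 standing at 10.99 and 10.08, beside 11.53 and 10.65 in sham, and replicates 3 to 5 at 5.74, 6.84 and 4.62.

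Fatty acid oxidation genes fell in 18 of 21 (19 lower and 1 higher adjusted over the list alone), led by Fabp1 (-3.03 ± 0.47), the hepatocyte fatty acid binding protein, Acaa1b (-2.45 ± 0.37) and Vnn1 (-2.43 ± 0.40). In camera, the oxidation genes moved down (adjusted p = 1.7e-17). Of 18 pericentral genes 13 fell (15 adjusted over the list alone), with Cyp1a2 (-3.41 ± 0.66) and Cyp2c50 (-2.65 ± 0.38). In camera, pericentral genes moved down (adjusted p = 2.33e-16). Bile acid synthesis genes fell in 10 of 16 (10 lower and 1 higher adjusted over the list alone), with Cyp7b1 (-2.86 ± 0.33). In camera, bile acid synthesis moved down (adjusted p = 4.56e-09). Of 17 male-biased genes 9 fell and 1 rose (15 and 1 adjusted over the list alone), down in camera (adjusted p = 2.07e-16). Slc10a1 was at -0.73 ± 0.27 (adjusted p = 0.0891). Secreted plasma proteins fell in 8 of 26 (8 adjusted over the list alone), Mbl2 (-1.98 ± 0.33) among them. In camera, secreted plasma proteins moved down (adjusted p = 1.7e-05, adjusted p = 0.193 with an estimated correlation).

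Of 15 cholangiocyte markers 9 rose (9 adjusted over the list alone), led by Cd24a (1.93 ± 0.24), the mucin Muc1 (1.54 ± 0.24) and Sox9 (1.49 ± 0.31), with Krt19 (0.69 ± 0.16) also higher. In camera, cholangiocyte markers moved up (adjusted p = 1.41e-08). Cell cycle genes rose in 17 of 26 (22 adjusted over the list alone), with the cyclin Ccnd1 (1.73 ± 0.34), Mcm3 (1.42 ± 0.24), a subunit of the replicative helicase, and Mki67 (1.31 ± 0.29). In camera, cell cycle genes moved up (adjusted p = 2.39e-13, adjusted p = 0.0651 with an estimated correlation). Of 25 acute phase genes 16 rose (23 adjusted over the list alone), Saa3 (2.64 ± 0.47), Cd14 (2.59 ± 0.38) and Lcn2 (2.42 ± 0.49) leading. In camera, acute phase genes moved up (adjusted p = 2.33e-16). Monocyte-derived macrophage markers rose in 9 of 15 (12 adjusted over the list alone), Cd68 (1.85 ± 0.29) among them. In camera, the macrophage markers moved up (adjusted p = 2.02e-11). Of 12 Kupffer cell markers 4 rose (8 adjusted over the list alone), up in camera (adjusted p = 2.28e-05, adjusted p = 0.193 with an estimated correlation). Matrix and stellate cell genes rose in 7 of 28 (10 adjusted over the list alone), Col1a1 (2.21 ± 0.63) and Timp1 (1.27 ± 0.31) included. In camera, the matrix genes moved up (adjusted p = 3.25e-05, adjusted p = 0.279 with an estimated correlation). Col1a2 was at 1.52 ± 0.52 and Acta2 at 0.65 ± 0.34. Of 19 cholesterol synthesis genes 14 rose (15 adjusted over the list alone), with Lss (2.38 ± 0.38) and Sqle (2.15 ± 0.40). In camera, the list moved up (adjusted p = 4.56e-11, adjusted p = 0.127 with an estimated correlation).

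S100a8 was at 0.59 ± 0.43, but neutrophil markers passed, up, as at day 7. Hepatocyte transcription factors fell in 3 of 19 and rose in 1 (3 and 1 adjusted over the list alone), down in camera (adjusted p = 0.00958, adjusted p = 0.0651 with an estimated correlation). Lymphocyte markers had a median of -0.27 and no called member. In camera they moved down (adjusted p = 0.0178, adjusted p = 0.232 with an estimated correlation). So did adipocyte markers, but not against all 9 sham arrays. Glul (-1.36 ± 0.36) and Cyp2e1 (-0.74 ± 0.13) fell. Cyp3a11 (-0.09 ± 0.22), Abcb11 (0.47 ± 0.27), Abcc4 (0.19 ± 0.18), Nr0b2 (1.13 ± 0.43), Krt7 (0.46 ± 0.25) and Alb (0.02 ± 0.08) did not pass.

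At day 3, 22 lists passed, 9 of them with an estimated correlation, and 1493 genes changed, 951 higher and 542 lower in BDL, 291 and 166 of them by at least 2-fold. With each array centred on its median the split was 794 and 752. The sham group has 2 arrays, and the count was 881 without sham day 3 replicate 1 and 668 without replicate 2. It was 921 with only day 3 arrays in the fit and 3481 against all 9 sham arrays. Calls that ended on leaving out 1 array were those of Obp2a (without sham day 3 replicate 2, adjusted p up to 0.188), Cyp7a1 (without BDL day 3 replicate 3, 4 or 5 or sham day 3 replicate 1 or 2, up to 0.204), Krt19 (without sham day 3 replicate 1, up to 0.0658), Ccnd1 (without sham day 3 replicate 1, up to 0.0902), Mki67 (without sham day 3 replicate 1, up to 0.0677), Lcn2 (without sham day 3 replicate 2, up to 0.170), Col1a1 (without BDL day 3 replicate 3 or sham day 3 replicate 1 or 2, up to 0.184), Timp1 (without sham day 3 replicate 2, up to 0.111), Sqle (without sham day 3 replicate 1, up to 0.169) and Glul (without sham day 3 replicate 1 or 2, up to 0.0998). With only day 3 arrays those of Cyp7a1, Cyp1a2, Krt19, Sqle and Glul were lost (adjusted p up to 0.221). Without replicate 1 Lss was at 1.58 and Sqle at 0.91, and the transcription factor, lymphocyte and sinusoidal export lists no longer passed (adjusted p = 0.0553, 0.10 and 0.149). The fatty acid synthesis list did not pass without BDL day 3 replicate 1, 4 or 5 or sham day 3 replicate 2 (up to 0.485). Without replicate 2 Sqle was at 3.39 and Lcn2 at 1.45. With the mean of its rows Cd24a was at 1.02, and against all 9 sham arrays Vnn1 was at -1.49. Alternatives added the calls of Slc10a1 (after cyclic loess, adjusted p = 0.0380), Col1a2 (in 2 settings, down to 0.00645), Acta2 (against all 9 sham arrays, 0.0263), Abcc4 (against all 9 sham arrays, 0.00914), Nr0b2 (in 2 settings, down to 0.0319) and Krt7 (in 2 settings, down to 0.0129).

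At day 7 Sprr1a (log2 fold change 5.34 ± 0.42 SE, as for the genes that follow) rose to 9.97 ± 0.41 (SD, n = 5) from 4.63 ± 0.30 (SD, n = 4) in sham, a rise of at least 4.97 from the filter level. Other large rises were those of Cd14 (3.90 ± 0.31), Ly6d (3.59 ± 0.38), Chil3 (3.25 ± 0.39), Cib3 (3.01 ± 0.33) and the acute phase protein Orm3 (3.00 ± 0.51). Gpnmb (2.96 ± 0.27), Sult1e1 (2.95 ± 0.45), Lcn2 (2.95 ± 0.39), which binds bacterial siderophores, and Mmp12 (2.90 ± 0.21), the macrophage elastase, rose as well. The largest falls were those of Hsd3b5 (-6.68 ± 0.41), Slco1a1 (-5.31 ± 0.34), the pseudogene Serpina4-ps1 (-5.14 ± 0.67), Sult2a8 (-4.84 ± 0.25) and Mup21 (-4.44 ± 0.33). Elovl3 (-3.68 ± 0.43), Moxd1 (-3.42 ± 0.76), Mup-ps12 (-3.16 ± 0.46), Dio1 (-2.62 ± 0.32), which activates thyroid hormone, and Cyp4a12a (-2.50 ± 0.33) fell too. All 20 genes had an adjusted p of 0.00156 or less in limma, with 5 BDL and 4 sham arrays. A group mean lay under 5 for Sprr1a, Chil3, Gpnmb, Sult1e1, Mmp12, Hsd3b5, Mup21, Moxd1 and Mup-ps12, and among list members for Timp1, Top2a, Cd79a and S100a8. Cyp8b1 (-1.62 ± 0.38) fell, while Cyp7a1 was at 0.87 ± 0.79 (adjusted p = 0.503).

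Of 15 cholangiocyte markers 14 rose (14 adjusted over the list alone), with Muc1 (1.47 ± 0.19) and Bicc1 (1.40 ± 0.19), and with Krt19 (0.70 ± 0.13), Krt7 (0.60 ± 0.20) and Sox9 (1.01 ± 0.25). Camera placed cholangiocyte markers up (adjusted p = 6.3e-10). Matrix and stellate cell genes rose in 21 of 28 (26 adjusted over the list alone), with Timp1 (1.87 ± 0.25) and the fibrillar collagen genes Col3a1 (2.07 ± 0.37), Col1a1 (2.06 ± 0.51) and Col1a2 (1.49 ± 0.42). Camera placed the matrix genes up (adjusted p = 2.71e-11, adjusted p = 0.114 with an estimated correlation). Acta2 (1.05 ± 0.27), the smooth muscle actin of activated stellate cells, rose. Of 15 monocyte-derived macrophage markers 14 rose (15 adjusted over the list alone), up in camera (adjusted p = 2.19e-17). Kupffer cell markers rose in 11 of 12 (11 adjusted over the list alone), with Marco (2.86 ± 0.27) and Cd5l (1.76 ± 0.25). Camera placed Kupffer cell markers up (adjusted p = 6.41e-10, adjusted p = 0.0870 with an estimated correlation). Of 23 cytokines and adhesion molecules 17 rose (18 adjusted over the list alone), Ccl2 (2.70 ± 0.26), Vcam1 (1.88 ± 0.21) and Icam1 (1.74 ± 0.18) first. Camera placed this group up (adjusted p = 3.44e-13). Cell cycle genes rose in 22 of 26 (25 adjusted over the list alone), with Ccnb2 (1.66 ± 0.23), Top2a (1.64 ± 0.27) and Mki67 (1.61 ± 0.23). Camera placed cell cycle genes up (adjusted p = 2.41e-13, adjusted p = 0.0824 with an estimated correlation). Of 25 acute phase genes 18 rose (18 adjusted over the list alone), up in camera (adjusted p = 2.16e-10, adjusted p = 0.0954 with an estimated correlation). The sinusoidal exporters Abcc1 (0.83 ± 0.16), Abcc4 (0.82 ± 0.15) and Abcc3 (0.76 ± 0.13) rose.

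Male-biased genes fell in 11 of 17 and rose in 1 (11 and 1 adjusted over the list alone), down in camera (adjusted p = 6.15e-13). Of 21 fatty acid oxidation genes 10 fell (13 lower and 1 higher adjusted over the list alone), Fabp1 (-2.10 ± 0.38) first. Camera placed the oxidation genes down (adjusted p = 2.4e-07, adjusted p = 0.0870 with an estimated correlation). Cyp2e1 (-0.45 ± 0.11) fell. Bile acid synthesis genes fell in 6 of 16 and rose in 1 (7 and 1 adjusted over the list alone), Cyp7b1 (-2.12 ± 0.26) first. Camera placed bile acid synthesis down (adjusted p = 0.00106, adjusted p = 0.189 with an estimated correlation). Slc10a1 (-0.75 ± 0.22) fell. Ppara (-0.99 ± 0.14) fell and Nr1i2 (0.66 ± 0.14), the pregnane X receptor, rose.

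Of 13 lymphocyte markers 4 fell (4 adjusted over the list alone), Cd79a (-0.74 ± 0.18) among them. Camera placed lymphocyte markers down (adjusted p = 0.000723, adjusted p = 0.116 with an estimated correlation). Interferon response genes rose in 6 of 17 (6 adjusted over the list alone), with the chemokines Cxcl10 (1.85 ± 0.38) and Cxcl9 (1.79 ± 0.40). Camera placed the list up (adjusted p = 0.00346, adjusted p = 0.340 with an estimated correlation). S100a8 (1.18 ± 0.34) rose. Cholesterol synthesis had 1 gene of 19 higher and 3 lower (1 and 3 adjusted over the list alone). Its median was 0.16, against a camera direction of down (adjusted p = 0.836). Sinusoidal endothelial markers had a median of 0.12 (adjusted p = 0.940) with no member past the threshold. Glul (-0.57 ± 0.29), Cyp3a11 (0.49 ± 0.18), Abcb11 (0.26 ± 0.21), Nr0b2 (0.02 ± 0.35) and Alb (0.07 ± 0.07) did not pass.

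At day 7, 22 lists passed, 4 of them with an estimated correlation, and 2819 genes changed, 2088 higher and 731 lower in BDL, 472 and 89 of them by at least 2-fold. The split was 1707 higher and 1346 lower after quantile normalization and 1897 and 1169 after cyclic loess. With each array centred on its median it was 1527 and 1908, a scaling that moved the median log2 fold change of all genes by -0.128, to -0.103. Against all 9 sham arrays 4375 genes changed. Without 1 array the call ended for Krt7 (without sham day 7 replicate 2, 3 or 4 or BDL day 7 replicate 2 or 4, adjusted p up to 0.144) and Col1a2 (without sham day 7 replicate 2 or 4, up to 0.0871). Sham day 7 replicate 1 had Col1a1 at 10.43, above each BDL day 7 array (9.22 to 9.99) and the other sham arrays (6.16 to 7.38). Without it Col1a1 was at 3.03 and Col1a2 at 2.29, and with only day 7 arrays both calls ended (adjusted p up to 0.0969). Krt7 also lost its call under each of the 3 scalings. With the mean of its rows Col1a2 was at 0.97, and against all 9 sham arrays Orm3 was at 1.98. Calls were gained by Cyp7a1 (with only the groups compared, adjusted p = 0.0131), Glul (in 3 settings, down to 0.0147) and Cyp3a11 (in 9 settings, down to 0.00132).

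**Figure D2:**
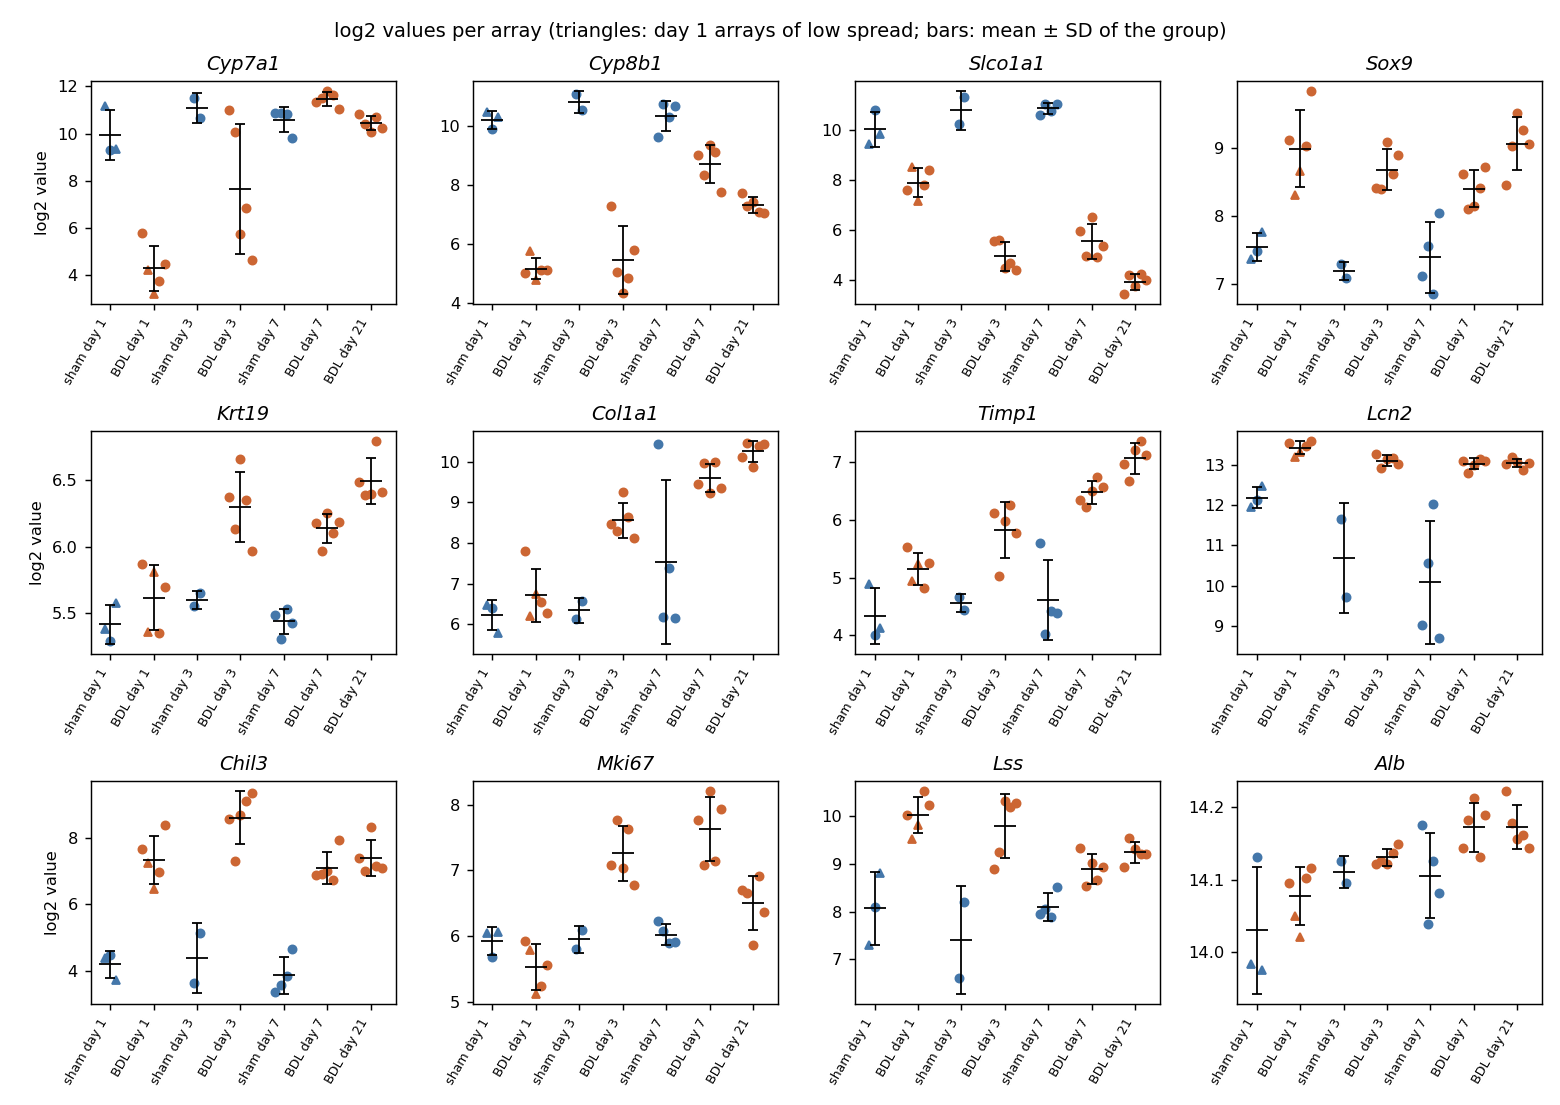
log2 values of 12 genes (y axis) on each of the 29 arrays by group (x axis), sham in blue and BDL in orange, with bars for the mean ± SD of each group and triangles for the 4 day 1 arrays of low spread. Cyp8b1 is lower in BDL than in sham at days 1, 3 and 7, and Sox9 is higher, while Alb differs by at most 0.07 between BDL and sham of the same day.

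At day 21, against the sham arrays of day 7, Sprr1a (log2 fold change 5.66 ± 0.42 SE, as for the genes that follow) rose to 10.29 ± 0.68 (SD, n = 5) from 4.63 ± 0.30 (SD, n = 4), a rise of at least 5.29 from the filter level. Sult1e1 (4.40 ± 0.45), Cd14 (4.40 ± 0.31), Chil3 (3.56 ± 0.39), Gpnmb (3.46 ± 0.27) and Mfge8 (3.42 ± 0.24), which helps phagocytes take up dying cells, rose too. So did Cybb (3.2 ± 0.39), a subunit of the phagocyte oxidase, the carboxypeptidase Cpe (3.19 ± 0.36), Cib3 (3.18 ± 0.33) and Orm3 (3.16 ± 0.51). Sult2a8 (-7.33 ± 0.25) fell from 11.02 ± 0.36 (SD, n = 4) to 3.68 ± 0.28 (SD, n = 5), a fall of at least 6.02 to that level. Slco1a1 (-6.93 ± 0.34), Hsd3b5 (-6.68 ± 0.41), Serpina4-ps1 (-6.16 ± 0.67), Elovl3 (-5.90 ± 0.43) and Mup21 (-5.68 ± 0.33) fell too, as did Cyp4a12a (-5.04 ± 0.33), Mup-ps12 (-4.07 ± 0.46), Fabp1 (-3.65 ± 0.38) and Mup3 (-3.63 ± 0.18). No adjusted p among these 20 genes exceeded 2.52e-05 in limma. Means under 5 were found for Sprr1a, Sult1e1, Chil3, Gpnmb, Sult2a8, Slco1a1, Hsd3b5, Serpina4-ps1, Mup21, Cyp4a12a and Mup-ps12, and in the lists for Timp1, Prom1, Ccl3, S100a8 and Jchain. Cyp8b1 (-3.02 ± 0.38) fell, and Cyp7a1 was at -0.14 ± 0.79 (adjusted p = 0.921).

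Of 28 matrix and stellate cell genes 27 rose (27 adjusted over the list alone), with Col1a1 (2.71 ± 0.51), Timp1 (2.45 ± 0.25), Col3a1 (2.38 ± 0.37) and Col1a2 (2.25 ± 0.42). In camera, the matrix genes moved up (adjusted p = 5.83e-16, adjusted p = 0.0651 with an estimated correlation). Acta2 (0.87 ± 0.27) rose. Cholangiocyte markers rose in 13 of 15 (14 adjusted over the list alone), with Bicc1 (2.08 ± 0.19), Prom1 (2.06 ± 0.29), Cd24a (1.81 ± 0.19) and Sox9 (1.68 ± 0.25). In camera, cholangiocyte markers moved up (adjusted p = 1.56e-11). Krt19 (1.05 ± 0.13) and Krt7 (0.94 ± 0.20) rose. Of 15 monocyte-derived macrophage markers 15 rose (15 adjusted over the list alone), up in camera (adjusted p = 1.58e-17). Kupffer cell markers rose in 11 of 12 (11 adjusted over the list alone), with Marco (2.40 ± 0.27), C1qb (2.06 ± 0.27) and Csf1r (1.68 ± 0.23). In camera, Kupffer cell markers moved up (adjusted p = 7.51e-09, adjusted p = 0.0982 with an estimated correlation). Of 23 cytokines and adhesion molecules 17 rose (17 adjusted over the list alone), Ccl2 (2.52 ± 0.26) and Ccl3 (1.91 ± 0.19) among them. In camera, this group moved up (adjusted p = 2.83e-11). Acute phase genes rose in 17 of 25 (18 adjusted over the list alone), Lcn2 (2.97 ± 0.39) included. In camera, acute phase genes moved up (adjusted p = 3.31e-10, adjusted p = 0.0982 with an estimated correlation). Of 5 sinusoidal exporters 4 rose (4 adjusted over the list alone), with Abcc1 (0.96 ± 0.16), Abcc3 (0.95 ± 0.13) and Abcc4 (0.84 ± 0.15). In camera, sinusoidal exporters moved up (adjusted p = 0.00111, adjusted p = 0.0651 with an estimated correlation). Neutrophil markers rose in 6 of 13 (7 adjusted over the list alone), S100a8 (1.04 ± 0.34) among them. In camera, the list moved up (adjusted p = 0.0131, adjusted p = 0.299 with an estimated correlation).

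Of 17 male-biased genes 15 fell and 1 rose (15 and 1 adjusted over the list alone), with a median of -2.77. In camera, male-biased genes moved down (adjusted p = 4.21e-19). Pericentral genes fell in 12 of 18 (12 adjusted over the list alone), Cyp2c37 (-1.83 ± 0.21) first and Cyp2e1 (-0.85 ± 0.11) included. In camera, pericentral genes moved down (adjusted p = 3.7e-08, adjusted p = 0.0982 with an estimated correlation). Of 16 bile acid synthesis genes 8 fell and 2 rose (10 and 2 adjusted over the list alone), Cyp7b1 (-2.79 ± 0.26) among the falls. In camera, bile acid synthesis moved down (adjusted p = 0.000114, adjusted p = 0.120 with an estimated correlation). Slc10a1 (-1.0 ± 0.22) fell. Fatty acid synthesis genes fell in 6 of 18 (6 lower and 1 higher adjusted over the list alone), with Thrsp (-1.40 ± 0.27) and Mlxipl (-1.28 ± 0.25). In camera, fatty acid synthesis moved down (adjusted p = 0.00277, adjusted p = 0.368 with an estimated correlation). Of 14 clock genes 7 fell and 2 rose (7 and 2 adjusted over the list alone), Npas2 (1.73 ± 0.37) and Arntl (1.58 ± 0.49) higher and Dbp (-1.68 ± 0.43) lower. In camera, clock genes moved down (adjusted p = 0.00970, adjusted p = 0.0982 with an estimated correlation). BDL day 21 replicate 1 stood apart in these 3, with log2 values of 5.41, 5.72 and 10.05. The clock list did not pass with centred arrays or against sham days 1 and 3 (adjusted p = 0.0647 and 0.0706).

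Cell cycle genes did not pass as a list (median 0.28, adjusted p = 0.239), and 3 of 26 rose (3 adjusted over the list alone). Mki67 was at 0.48 ± 0.23 (adjusted p = 0.137). Of 13 lymphocyte markers 2 rose and 3 fell (2 and 3 adjusted over the list alone), Jchain (1.37 ± 0.19), which joins immunoglobulin subunits, being higher. Their median was 0.02, against a camera direction of down (adjusted p = 0.716). Glul (-1.11 ± 0.29) fell. Cyp3a11 (0.36 ± 0.18), Abcb11 (0.12 ± 0.21), Nr0b2 (0.16 ± 0.35) and Alb (0.07 ± 0.07) did not pass.

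Altogether 19 lists passed, 4 of them with an estimated correlation, and 3698 genes changed at day 21, 2537 higher and 1161 lower, 609 and 162 of them by at least 2-fold. The split was 2065 and 1966 after quantile normalization and 2347 and 1675 after cyclic loess. It was 1799 and 2615 with each array centred on its median, which moved the median of all genes by -0.134. Against the sham arrays of days 1 and 3 the fatty acid synthesis list had a median of 0.12, above 0, and -0.21 against sham day 7. The calls of Thrsp (-0.25), Arntl (1.0) and Dbp (-0.73) ended against sham days 1 and 3 (adjusted p up to 0.470), with Lcn2 at 1.46, Orm3 at 1.32 and Acta2 at 1.62. With only the groups compared those of Acta2 and S100a8 ended (up to 0.0592). On leaving out 1 array the call ended for Acta2 (without sham day 7 replicate 2, 3 or 4 or BDL day 21 replicate 4, adjusted p up to 0.0955), S100a8 (without sham day 7 replicate 2 or 3 or BDL day 21 replicate 2 or 4, up to 0.0981) and Arntl (without sham day 7 replicate 3, up to 0.0540). The neutrophil list did not pass without BDL day 21 replicate 4 (adjusted p = 0.0507), and without sham day 7 replicate 1 Col1a1 was at 3.68. Against all 9 sham arrays Thrsp was at -0.76. Alternatives gave calls for Mki67 (in 3 settings, 1 of them without BDL day 21 replicate 3, adjusted p down to 0.0273) and Cyp3a11 (in 4 settings, down to 0.00652).

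**Figure D3:**
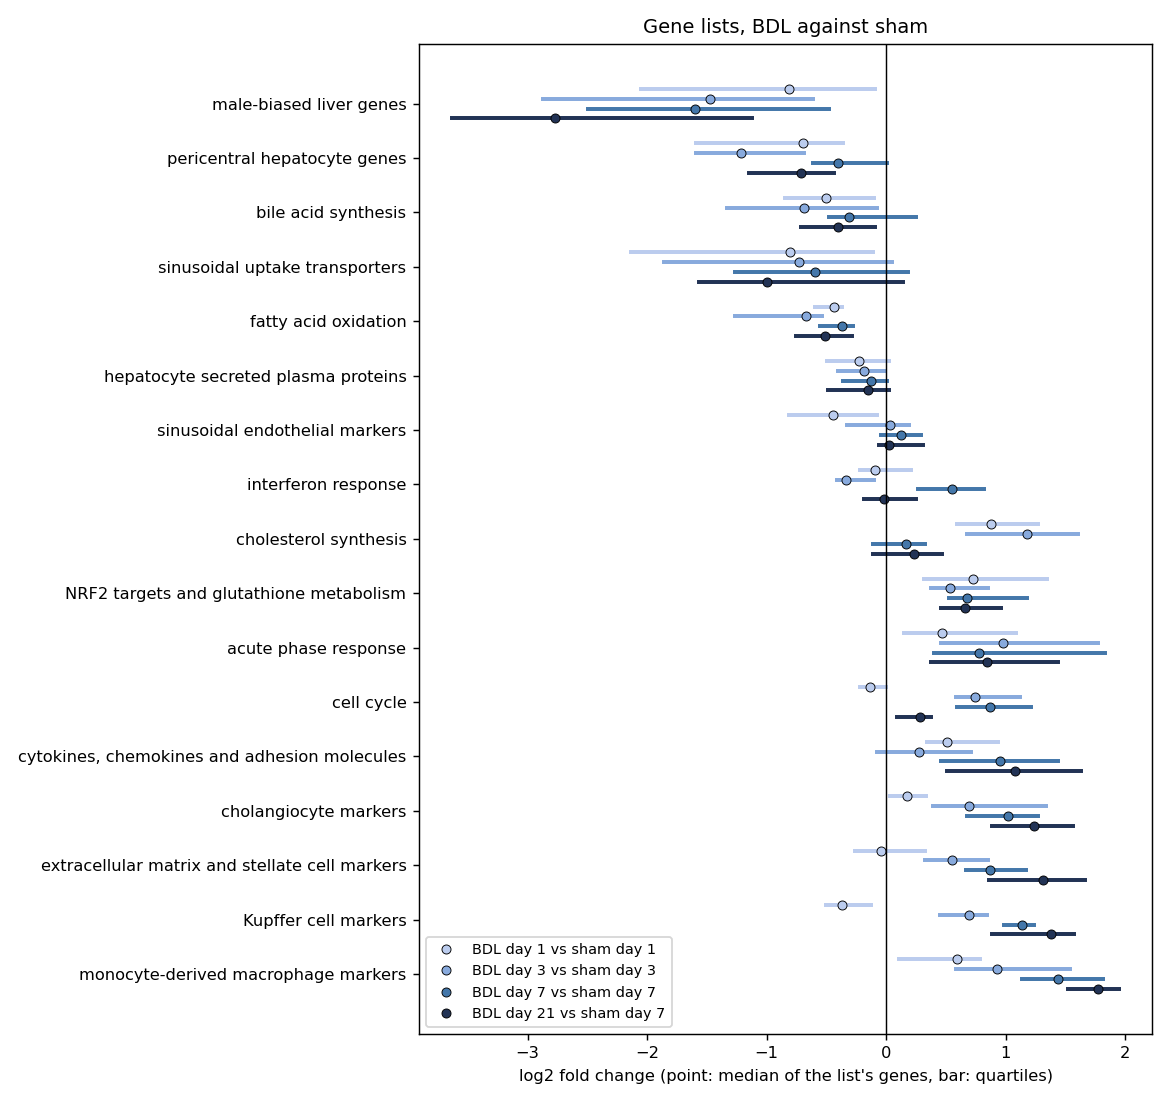
Median log2 fold change (x axis, points) with quartiles (bars) of 17 gene lists (y axis) in the 4 comparisons of BDL with sham, darker for later days. The median of the monocyte-derived macrophage markers was 0.59 at day 1 and 1.78 at day 21 against sham day 7, and that of the male-biased liver genes -0.82 and -2.77.

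The effect of BDL at day 7 was then tested against its effect at day 1, each against its own sham. Cyp7a1 (log2 fold change 6.52 ± 1.17 SE, as for the genes that follow) led, its effect being -5.65 at day 1 and 0.87 at day 7. Car3 (3.46 ± 0.97), Cyp8b1 (3.44 ± 0.57), Serpina6 (3.01 ± 0.82) and Atp6v0d2 (2.69 ± 0.50) followed in that direction. The effect was lower at day 7 for Serpina4-ps1 (-4.08 ± 1.0), Mup21 (-3.40 ± 0.48), Slco1a1 (-3.17 ± 0.50), Elovl3 (-2.45 ± 0.64) and Cidec (-2.02 ± 0.58), a lipid droplet protein. In limma these 10 genes had an adjusted p of up to 0.0432. A group mean under 5 entered for Cyp7a1, Atp6v0d2 and Mup21, and in a list for Mmp12. At day 7 cell cycle genes had a higher effect in 13 of 26 (23 adjusted over the list alone), Mki67 (2.01 ± 0.34) first. In camera, cell cycle genes moved up (adjusted p = 4.9e-17, adjusted p = 0.0740 with an estimated correlation). Kupffer cell markers had a higher effect at day 7 in 10 of 12 (11 adjusted over the list alone), with Cd5l (2.26 ± 0.36). In camera, Kupffer cell markers moved up (adjusted p = 3.83e-14, adjusted p = 0.0740 with an estimated correlation). At day 7 matrix and stellate cell genes had a higher effect in 11 of 28 (17 adjusted over the list alone), with Col3a1 (2.15 ± 0.54). In camera, the matrix genes moved up (adjusted p = 1.15e-12, adjusted p = 0.167 with an estimated correlation). Monocyte-derived macrophage markers had a higher effect at day 7 in 6 of 15 (11 adjusted over the list alone), with Mmp12 (2.33 ± 0.31). In camera, the macrophage markers moved up (adjusted p = 3.6e-10, adjusted p = 0.0740 with an estimated correlation).

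Stress response (2 of 17), male-biased (5 of 17) and fatty acid synthesis genes (1 of 18) also had a lower effect at day 7 (6, 6 and 3 adjusted over the list alone). Their adjusted p in camera was 2.25e-05, 0.00301 and 0.0103, against an adjusted p of 0.167, 0.352 and 0.585 with an estimated correlation. Interferon response (1 of 17), pericentral (2 of 18) and cytokine genes (3 of 23) had a higher one (3, 6 and 7 adjusted over the list alone). Here camera gave an adjusted p of 0.00452, 0.0127 and 0.0333, and an adjusted p of 0.536, 0.585 and 0.536 with an estimated correlation. For Krt19 (0.50 ± 0.19), Col1a1 (1.57 ± 0.75), Timp1 (1.05 ± 0.37), Lcn2 (1.71 ± 0.58), S100a8 (-0.54 ± 0.50) and Slc10a1 (0.34 ± 0.32) the difference did not pass. In all 637 genes differed between the days, 511 with a higher and 126 with a lower effect at day 7. With the array set as a term 1076 did (856 and 220). None of the 13 lists that passed did so with an estimated correlation, and 12 did with the array set as a term, fatty acid synthesis not (adjusted p = 0.0537). That term moved the interferon median most, from 0.56 to 0.89. The split was 435 and 258 after quantile normalization and 395 and 302 with arrays centred on their medians. Without the 4 arrays of low spread, which leaves a lone sham day 1 array, 287 genes differed, and Cyp7a1 (5.53), Car3 (3.39), Serpina6 (3.11), Atp6v0d2 (1.45), Serpina4-ps1 (-2.16), Elovl3 (-1.84), Cidec (-1.95), Mki67 (1.71) and Col3a1 (1.97) did not pass (adjusted p up to 0.454), nor did the cytokine, interferon, pericentral and male-biased lists (up to 0.556). With only the 4 groups the calls of Elovl3 and Col3a1 ended (up to 0.0658). Calls were gained for Col1a1 (without sham day 7 replicate 1, adjusted p = 0.00145), Timp1 (with array weights or without sham day 7 replicate 1, down to 0.0112) and Lcn2 (without sham day 7 replicate 3, 0.00295). Single left-out arrays ended the calls of Car3 (any of 12 of 17 arrays, adjusted p up to 0.0744), Serpina6 (any of 8 of 17 arrays, up to 0.0648), Serpina4-ps1 (without sham day 1 replicate 1, up to 0.0725), Elovl3 (without sham day 7 replicate 2 or 4 or sham day 1 replicate 1 or 3, up to 0.0832), Cidec (any of 13 of 17 arrays, up to 0.0893) and Col3a1 (without sham day 7 replicate 2 or 4, up to 0.0578). Lists that no longer passed were cytokines (any of 7 arrays, adjusted p up to 0.101), pericentral genes (sham day 7 replicate 1 or BDL day 1 replicate 3, up to 0.132) and fatty acid synthesis (sham day 1 replicate 1, 0.113).

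Between BDL arrays of days 3 and 1, Gpnmb (log2 fold change 2.62 ± 0.26 SE, as for the genes that follow) led the rises among genes whose arrays did not overlap. It was followed by Got1 (1.98 ± 0.29), a transaminase, Ect2 (1.93 ± 0.27), which acts in cell division, Ehd3 (1.89 ± 0.26) and Ly86 (1.86 ± 0.22). Mup21 (-4.45 ± 0.31), Elovl3 (-2.97 ± 0.41), Slco1a1 (-2.95 ± 0.32), Sult2a8 (-2.70 ± 0.24) and the small nucleolar RNA gene Snora74a (-2.57 ± 0.57) fell, and Snora74a was at -1.32 with the array set as a term and at -1.47 without its arrays. Cyp7a1 (3.36 ± 0.75), Slc10a1 (0.97 ± 0.20), Krt19 (0.68 ± 0.12) and Mki67 (1.73 ± 0.22) rose as well. Means under 5 occurred for Ect2, Mup21, Slco1a1, Sult2a8 and Cyp7a1. These 14 genes had an adjusted p of at most 0.00268 in limma. Sinusoidal endothelial markers rose in 13 of 15 (13 adjusted over the list alone), Mrc1 (1.77 ± 0.19) and Clec4g (1.61 ± 0.23) first. Camera placed endothelial markers up (adjusted p = 1.07e-12, adjusted p = 0.154 with an estimated correlation). Of 12 Kupffer cell markers 11 rose (11 adjusted over the list alone), C1qb (1.85 ± 0.26) first. Camera placed Kupffer cell markers up (adjusted p = 2.95e-11, adjusted p = 0.191 with an estimated correlation). Cell cycle genes rose in 19 of 26 (24 adjusted over the list alone), up in camera (adjusted p = 1.07e-12, adjusted p = 0.191 with an estimated correlation). Of 28 matrix and stellate cell genes 17 rose (20 adjusted over the list alone), Bgn (1.84 ± 0.23) first. Camera placed the matrix genes up (adjusted p = 2.95e-11, adjusted p = 0.222 with an estimated correlation). Cytokines and adhesion molecules fell in 8 of 23 and rose in 4 (10 and 5 adjusted over the list alone), Cxcl1 (-2.16 ± 0.31) and Tnfaip3 (-1.41 ± 0.15) falling most. Camera placed this group down (adjusted p = 0.00287, adjusted p = 0.285 with an estimated correlation). Altogether 12 lists passed camera, none of them with an estimated correlation, and 13 passed fry. With the array set as a term all 12 passed in the same direction, the interferon median moving most, from -0.30 to -0.55.

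In all 2715 genes changed from day 1 to day 3, 1769 higher and 946 lower. With the array set as a term 1479 did, 834 higher and 645 lower, and 1284 were called both ways. Without the 4 arrays of low spread the count was 1444, and without BDL day 1 replicate 3 alone 1718. The split was 1587 and 1412 after quantile normalization and 1362 and 1628 with centred arrays. No named call was lost on leaving out 1 array. The fatty acid oxidation list no longer passed without BDL day 3 replicate 3 or BDL day 1 replicate 5, nor the interferon list without BDL day 3 replicate 5 or BDL day 1 replicate 1 or 5 (adjusted p up to 0.155). With the mean of its rows Bgn was at 1.11.

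From day 3 to day 7 of BDL, Car3 (log2 fold change 4.40 ± 0.62 SE, as for the genes that follow) rose most, from 6.30 ± 1.99 (SD, n = 5) to 10.70 ± 0.67 (SD, n = 5). Cyp7a1 (3.82 ± 0.75), Serpina6 (3.27 ± 0.52), Cyp8b1 (3.26 ± 0.36) and H2-Ab1 (2.46 ± 0.30), a chain of the class II major histocompatibility complex, came next. Obp2a (-3.89 ± 0.72), Serpina4-ps1 (-2.31 ± 0.63), Fmo2 (-1.84 ± 0.34), Cux2 (-1.27 ± 0.21) and the complement gene C4a (-1.26 ± 0.29) fell most. For these 10 genes the highest adjusted p was 0.0283 in limma. Of 17 interferon response genes 11 rose (14 adjusted over the list alone), with Cxcl9 (2.10 ± 0.38), Bst2 (1.63 ± 0.28), Isg15 (1.5 ± 0.30), whose mean lay under 5 at day 3, and Ifit1 (1.45 ± 0.27). In camera, interferon response genes moved up (adjusted p = 2.92e-14, adjusted p = 0.0664 with an estimated correlation). Cytokines and adhesion molecules rose in 12 of 23 (13 adjusted over the list alone), with Il1b (2.08 ± 0.33). In camera, this group moved up (adjusted p = 1.71e-12). Altogether 14 lists passed, 1 of them (cytokines) with an estimated correlation.

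In all 837 genes changed from day 3 to day 7, 676 higher and 161 lower. The split was 471 and 286 after quantile normalization, 583 and 281 after cyclic loess and 440 and 338 with centred arrays. The count was 472 without BDL day 7 replicate 5, 556 without replicate 3 and 479 without BDL day 3 replicate 5. A term for the array set gave 1284. A single left-out array ended the call of Serpina4-ps1 (without BDL day 7 replicate 2, 3, 4 or 5 or BDL day 3 replicate 3 or 5, adjusted p up to 0.0824). The lists of cholangiocyte and cell cycle genes no longer passed without BDL day 3 replicate 5, nor that of bile acid synthesis without replicate 3, 4 or 5 (adjusted p up to 0.144).

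From day 7 to day 21 of BDL, rises included Igkv4-72 (log2 fold change 2.26 ± 0.30 SE, as for the genes that follow) for a kappa chain, Igh-VS107 (1.6 ± 0.20) for a heavy chain, Cpe (1.83 ± 0.34) and Jchain (1.71 ± 0.18). The largest falls were those of Cyp4a12a (-2.54 ± 0.31), Sult2a8 (-2.50 ± 0.24), Elovl3 (-2.22 ± 0.41), Mup3 (-2.03 ± 0.17) and Saa3 (-1.70 ± 0.36). Their adjusted p reached at most 0.0143 in limma, and a group mean lay under 5 for Igkv4-72, Jchain, Cyp4a12a and Sult2a8. Of 26 cell cycle genes 13 fell (20 adjusted over the list alone), Ccnb2 (-1.36 ± 0.21) first and Mki67 (-1.13 ± 0.22) included. Camera placed cell cycle genes down (adjusted p = 4.04e-35). Male-biased genes fell in 6 of 17 (13 adjusted over the list alone), down in camera (adjusted p = 1.46e-22). Of 13 lymphocyte markers 2 rose (3 adjusted over the list alone), Ighm (1.04 ± 0.17) included. Camera placed lymphocyte markers up (adjusted p = 4.82e-06, adjusted p = 0.0952 with an estimated correlation). No matrix gene passed over all genes (7 of 28 rose adjusted over the list alone), and their median was 0.37. Camera placed the matrix genes up (adjusted p = 9.3e-11, adjusted p = 0.206 with an estimated correlation). Col1a1 (0.65 ± 0.48), Krt19 (0.36 ± 0.12) and Cyp7a1 (-1.02 ± 0.75) did not pass. Altogether 12 lists passed, 2 of them with an estimated correlation, and 127 genes changed, 59 higher and 68 lower. The count was 59 without BDL day 7 replicate 3, 70 without replicate 1, and 65, 78 and 63 without BDL day 21 replicates 3, 4 and 5. A left-out array ended the call of Saa3 (without BDL day 7 replicate 1 or BDL day 21 replicate 4 or 5, adjusted p up to 0.0675). With the mean of its rows Igh-VS107 was at 1.04, and Cyp7a1 passed with only the groups compared (adjusted p = 0.00781).

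The sham groups, operated without ligation, were also compared over time, each against sham day 7. Acute phase genes rose in 10 of 25 (11 adjusted over the list alone) at day 1. In camera, acute phase genes moved up (adjusted p = 5.46e-10, adjusted p = 0.695 with an estimated correlation). They were led by the serum amyloid genes Saa2 (log2 fold change 2.90 ± 0.55 SE, as for the genes that follow) and Saa3 (2.82 ± 0.43), Orm2 (2.24 ± 0.34) and Lcn2 (2.11 ± 0.45). Snora74a (2.92 ± 0.69) and Snora31 (2.70 ± 0.60), small nucleolar RNA genes, rose too. Abcd2 (-1.95 ± 0.42), Tma7 (-1.91 ± 0.35), Ywhaq (-1.81 ± 0.45), Elovl6 (-1.43 ± 0.37) and Pklr (-1.41 ± 0.30) fell most. The 11 genes had an adjusted p of up to 0.0320 in limma. In all 604 genes changed, 169 higher and 435 lower.

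With the array set as a term 1 gene differed between sham day 1 and sham day 7, Orm2, 2 of the 3 sham day 1 arrays being of low spread. The other 10 named calls were lost, Saa2 (2.82), Saa3 (2.79), Lcn2 (2.21), Snora74a (0.82), Snora31 (1.14), Abcd2 (-1.58), Tma7 (-0.81), Ywhaq (-0.37), Elovl6 (-0.53) and Pklr (-0.87) (adjusted p up to 0.624). Without its arrays, which leaves a lone sham day 1 array, all 11 were lost, Saa2 (2.79), Saa3 (1.81), Orm2 (2.22), Lcn2 (2.05), Snora74a (0.36), Snora31 (0.95), Abcd2 (-1.50), Tma7 (-0.55), Ywhaq (-0.10), Elovl6 (-0.57) and Pklr (-1.02) (up to 0.956), as they were with only the 2 groups in the fit (up to 0.251). With the term the acute phase list passed, with a median of 0.68 against 0.28. Each of the 10 calls was also lost without sham day 1 replicate 3, and all but that of Saa3 without replicate 1, with adjusted p up to 0.247. The count of genes ran from 2 without sham day 1 replicate 3 (Orm2 and Xrcc5, the latter named after its value was seen) and 12 without replicate 1 to 3040 without replicate 2. It was 260, 311, 80 and 202 without sham day 7 replicates 1 to 4 in turn. The split of the 604 genes was 261 and 377 after quantile normalization, 228 and 276 after cyclic loess and 232 and 319 with centred arrays.

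Between sham day 3 and sham day 7 limma called 0 genes, with 627 at an unadjusted p under 0.05 where chance gives 735. Cyp7a1 was at 0.49 ± 1.02, Col1a1 at -1.19 ± 0.66 and Lcn2 at 0.61 ± 0.51. The count was 35 without sham day 3 replicate 1 and 5 without replicate 2, each leaving a lone array. Those 5 were Asic5, Hsd17b10, Slc27a1, Sqle and Stamos, named here after their values were seen. Adipocyte markers stood higher in sham day 3, with a median of 0.64, and 0 of 6 passed over all genes and 5 adjusted over the list alone. Camera placed the list up (adjusted p = 9.61e-07). Cholesterol synthesis had a median of -0.46. Camera placed it down (adjusted p = 5.6e-07, adjusted p = 0.717 with an estimated correlation). Its median was 0.20 without sham day 3 replicate 1. Altogether 10 lists passed, 1 of them with an estimated correlation and 1 with fry, with no member past the threshold over all genes. Leaving out 1 array ended 9 of these list calls (adjusted p up to 0.935).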

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

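The tests of an array batch, of hepatocyte share for the clock genes, of gene copies, of female-biased genes, and those with the array set as a term or without its arrays, were chosen only after the result was seen.

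Among named genes, 1 array lay apart from the rest of its group by Dixon's test in 22 of 385 gene and group pairs (5.71%). Chance gives about 1 in 20 groups, or 5%. In BDL day 1 the log2 values were Acaa1b at 7.59 (replicate 4), Got1 at 10.92 (replicate 1), S100a8 at 7.51 (replicate 5) and Slc10a2 at 8.20 (replicate 2). In BDL day 3 it was Ifit1 at 6.31 (replicate 2). In BDL day 7 they were Chil3 at 7.94 (replicate 5), Cyp7b1 at 9.02 (replicate 5), Elovl3 at 9.03 (replicate 1) and Mup3 at 12.84 (replicate 1). In BDL day 21 they were Arntl at 5.72 (replicate 1), Chil3 at 8.35 (replicate 3), Cib3 at 9.85 (replicate 3), Dbp at 10.05 (replicate 1), Krt19 at 6.79 (replicate 4) and Npas2 at 5.41 (replicate 1). In sham day 7 they were Abcc1 at 5.42 (replicate 4), Acta2 at 9.16 (replicate 1), Cd79a at 5.87 (replicate 2), Cxcl9 at 8.57 (replicate 1), Cyp7a1 at 9.81 (replicate 4), Slc10a1 at 11.63 (replicate 1) and Ywhaq at 10.88 (replicate 1).

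By the test of the difference itself, the effect of BDL differed between days 7 and 1 for 26 of 88 named genes and for 13 lists in camera, none of which passed with an estimated correlation. The difference of log2 fold changes, day 7 minus day 1, was above 0 for Atp6v0d2 (2.69), Bicc1 (1.32), Car3 (3.46), Ccnb2 (1.98), Cd5l (2.26), Col3a1 (2.15), Cyp2c50 (1.78), Cyp7a1 (6.52), Cyp8b1 (3.44), Gpnmb (2.23), Kdr (0.97), Mki67 (2.01), Mmp12 (2.33), Muc1 (1.28), Nr1h4 (0.63), Serpina6 (3.01), Sprr1a (2.39), Top2a (1.86) and Vcam1 (1.37). It was below 0 for Abcb1a (-1.56), Cidec (-2.02), Cyp4a12a (-1.90), Elovl3 (-2.45), Mup21 (-3.40), Serpina4-ps1 (-4.08) and Slco1a1 (-3.17). List medians of that difference were 0.73 for cholangiocyte markers, 0.93 for matrix and stellate cell genes, 1.47 for Kupffer cell markers, 0.89 for monocyte-derived macrophage markers, 0.62 for sinusoidal endothelial markers, 0.32 for cytokines and adhesion molecules, 0.56 for interferon response genes, 0.98 for cell cycle genes, 0.43 for pericentral genes, -0.10 for male-biased genes, -0.73 for cholesterol synthesis genes, -0.31 for fatty acid synthesis genes and -0.43 for unfolded protein and stress response genes.

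The 4 day 1 arrays of low spread stood apart in sham and BDL alike, and the shift between them and the other day 1 arrays correlated across genes between sham and BDL (r = 0.624; genes are not independent replicates). Picking the arrays by the spread they share fixes part of this value, so it decides nothing and a difference between array batches stays open. Tissue from outside the liver would raise its markers by about the size of the shift, and the largest median among 4 such lists was 0.228 (adipocyte markers), which argues against it. The arms of the clock differed between the array sets by 0.434 (95% -0.856 to 1.72), too wide to exclude another time of day at harvest. No biological explanation was tested, since the labels name no group that follows these arrays.

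At BDL day 21, clock genes of the output arm had a mean shift of -0.976 against sham day 7, and Arntl, Npas2 and Clock one of 1.06. As their levels in other cells were not measured, a lower share of hepatocyte RNA stays open. Harvest times are not given here, so their role stays open. Output minus activators shifted by -2.03, within the range of 2.45 over 9 sham arrays (-2.64, beyond it, without BDL day 21 replicate 1). It was 1.66 in that array, -1.73 to -1.09 in the other 4 and at least -0.688 in sham. At BDL day 1 it was -1.32 to 0.129. At day 7 the clock list passed camera, down, against its own sham. With centred arrays or all 9 shams its adjusted p was 0.0861 and 0.0533. Ligation or time after surgery stays open and untested at day 21.

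The male-biased liver genes fell at BDL day 21 against sham day 7, with a median of -2.77 (quartiles -3.63 to -1.13). A lower share of hepatocyte RNA would lower other hepatocyte genes alike, but the median of 44 such genes at log2 levels of 6 to 12 was -0.264 (quartiles -0.577 to 0.0997). Near-identical gene copies are not the whole cause either, since 10 genes outside 6 multigene families had a median of -2.09. A general loss of sex bias would raise female-biased genes, whose median was 0.436 over 9 genes (quartiles -0.600 to 0.665), which cannot be told apart from no shift because members went both ways. In camera these genes also fell at days 3 and 7 against sham of the same day, where time after surgery is matched. At day 21 an effect of ligation stays a hypothesis, with time after surgery open beside it.

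Other splits of the same arrays were counted for each comparison of groups of at least 3. For BDL against sham at day 1, 5 of 56 splits gave as many genes as the real one (1958), the highest other giving 2704, so chance is not excluded. The 4 splits with more genes follow the array set, parting its arrays 1 against 3 or 4 against 0. Exchanging arrays within the sets, with the set as a term, 1 of 24 splits gave as many (2184, highest other 849). The sets were chosen afterwards, so chance is not excluded. In 100 splits each, 1 gave as many at day 7 (2819, highest other 2099), day 21 (3698, 2618), and between successive days of BDL (2715 and 829, 837 and 65, 127 and 5), so chance is excluded. Of 35 splits of sham days 1 and 7, 2 gave as many (604, highest other 1196), so it is not, and the higher split also keeps both arrays of low spread together, the value with the set as a term being 1. For the difference of the effects at days 7 and 1, 4 of 100 splits gave as many (637, highest other 2815). The 3 higher splits exchange most day 7 BDL and sham arrays and so carry the effect of BDL itself. Such splits are no reference for a difference of effects and do not exclude chance.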

How the results depend on the processing

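The array set as a term and the fits without or within its arrays were chosen only after the data were seen. Leaving out the GAPDH control probe sets and leaving out cross-hybridising probe sets were not run, since the identifiers are numbers that mark neither. No paired analysis was possible because replicate numbers are accession order. A lone array, as sham day 3 with 1 left out or sham day 1 without the array set, is assumed to vary like the other groups. Array number and, at low levels, signal over background limit what could be called. Unless said otherwise, the cause of a shift was not tested.

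No gene result past the threshold here or in an alternative changed sign between them. Of 316 gene results, 24 called ones no longer passed with only the groups compared, where fewer arrays estimate the spread, and 32 without the 4 arrays of low spread, and 7 of 60 at day 1 within them. With quantile, cyclic loess or median scaling 1 did in each, Krt7 at day 7. Calls ended too for Timp1 at day 1 and Cidec in the difference of effects without the filter, for Timp1 and Car3 with array weights, and with a mean-variance trend for Car3, Serpina6 and Cidec in that difference and Serpina4-ps1 from BDL day 3 to 7. Of 144 list calls, 3 were lost with the array set as a term, 9 without its arrays, 11 with the stricter filter and 7 with array weights.

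Counts of genes with only the groups compared were 704 at day 1, 921 at day 3, 1779 from BDL day 1 to 3, 235 from 7 to 21, and 0 in limma between sham days 1 and 7, where 2237 had an unadjusted p under 0.05. Against all 9 sham arrays they were 3198, 3481 and 4375 at days 1, 3 and 7. Array weights gave 1845 from BDL day 3 to 7, 463 from 7 to 21 and 1879 between sham days 1 and 7, and a level above 6 in at least 5 arrays gave 78 from BDL day 7 to 21. With the array set as a term they were 1479 from BDL day 1 to 3, 1284 from 3 to 7, 1 between sham days 1 and 7 and 1076 for the difference of effects. Without its 4 arrays they were 597 at day 1, 1444, 1308, 1 (Rny3, named after its value was seen) and 287 in those 4.

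Leaving out 1 array gave 1268 to 2750 genes at day 1 (lowest without sham day 1 replicate 1), 668 to 1692 at day 3 (sham day 3 replicate 2), 1718 to 3054 from BDL day 1 to 3 (BDL day 1 replicate 3), 472 to 964 from 3 to 7 (BDL day 7 replicate 5), 59 to 133 from 7 to 21 (BDL day 7 replicate 3), 2 to 3040 between sham days 1 and 7 and 0 to 35 between sham days 3 and 7, the 0 from limma. It gave 2267 to 2822 at day 7, 3120 to 3571 at day 21 and 444 to 739 for the difference of effects.

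With an estimated correlation the lists passing camera went from 16 to 0 at day 1, 22 to 9 at day 3, 22 to 4 at day 7, 19 to 4 at day 21, 12 to 0, 14 to 1 and 12 to 2 between successive days of BDL, 4 to 0 and 10 to 1 for sham days 1 and 3 against 7, and 13 to 0 for the difference of effects. Fry called 5 from BDL day 7 to 21, 1 and 1 for sham days 1 and 3, and 7 for the difference. Between sham days 3 and 7 array weights gave 6 lists, and leaving out 1 array 1 to 13. Between sham days 1 and 7 the array set as a term gave 8. On leaving out 1 array the camera direction reversed, between sham days 3 and 7, for the matrix (-0.318 to -0.106, -0.106 without sham day 7 replicate 1) and acute phase genes (-0.0274 to 0.362, -0.0274 without sham day 7 replicate 4) and, without sham day 3 replicate 1, for fatty acid oxidation (-0.0514 to 0.186, there -0.0514) and cholesterol synthesis (-1.22 to 0.201, there 0.201). The values are list medians. Fatty acid synthesis at day 21 reversed, being at 0.122 against sham days 1 and 3.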

Other observations

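Periportal hepatocyte genes, which hold the enzymes of the urea cycle and gluconeogenesis, did not pass camera in any comparison of BDL with sham. Of 17, 2 rose and 4 fell at day 1 (3 and 6 adjusted over the list alone), 2 and 1 at day 3 (2 and 1), and 2 and 0 at day 7 and at day 21 against sham day 7 (2 and 0). Their medians were -0.27, 0.32, 0.02 and 0.13 (adjusted p = 0.157, 0.367, 0.940 and 0.932), and the means at days 7 and 21 were below 0 (-0.01 and -0.02).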
